A study of Neurospora crassa with 16 samples.

How the data were processed

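The samples were grouped by their titles, which give the strain and Pi of both channels, the dye orientation and a number from 1 to 4. This made 4 groups of 4 arrays from 2 comparisons, WT (FGSC 2489) low against high Pi and the *mak-2* deletion strain (FGSC 11482) against WT at low Pi. Per the labels, mycelia grew for 5 h at 30 °C in Fries medium at pH 5.4, and total RNA was labelled with Cy3 and Cy5. On the 4 arrays with *mak-2* RNA in Cy5, one characteristic of the WT channel says high Pi, while the title, the source name and the series design say low Pi. These arrays were grouped by title, and as an alternative they were left out, with the dye effect of the *mak-2* arrays in Cy3 then taken from the WT arrays. The labels do not say whether arrays of opposite dye with one number carried the same extracts, nor whether both comparisons shared WT low Pi extracts.

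Per the file headers, the scans were made on a GenePix 4000B scanner at 635 and 532 nm and read with GenePix Pro 6.1.0.2. The deposited scanner files give foreground and background as pixel intensity, and the share of pixels above background and of saturated pixels as a percentage. The value table of the authors holds log2 ratios, a scale not stated by the authors and read here from its slope of 1.11 to 1.18 against the log2 ratios computed from the scanner files, with array medians of −0.034 to 0.0272. Across genes its values correlated with those ratios at r = 0.954 to 0.990 once the sign of the WT comparison, high over low Pi, was turned. It was used as an alternative only. The tool that made the value table is not given in the sources used here.

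Each array had 11520 spots, 9428 of them for genes with NCU identifiers, 1067 clone-coded and 25 mitochondrial. Spots for ChIP tiling (384), spots marked empty (384 named and 204 unnamed), controls and transgenes (22), rRNA (3) and other alleles (3) were left out of the gene tests. Of 9217 NCU identifiers, 8150 matched a current locus tag and 18 an old one, and 1043 genes had a symbol. Names of spots marked empty were not used, and none of those spots stood above background on at least 8 arrays.

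The mean foreground and median background intensity of each channel were corrected with normexp (offset 50) and each array was normalized by loess over the gene spots, with no step between arrays. Spots flagged by the scanner software, 12 to 364 gene probes per array, were left out. A probe counted as above background where its foreground passed the background by 2 background SDs, and a gene was tested where this held in at least 1 channel on at least 8 of 16 arrays. The brightest probe stood for a gene. Of 95 genes with several measured probes, the probes differed by over 1 log2 unit in 12 genes in the WT comparison. In the *mak-2* comparison they did so in 17. A spot with at least 50% saturated pixels in a channel counted as saturated, and fold changes with a saturated or undetected side on all 8 arrays were given as bounds. With a saturated side the bound is the fitted fold, and with an undetected side it sets the brighter mean against the lowest signal above background or the probe's own, whichever is higher. These bounds do not cover the error of the fit or other normalizations. Of 10300 genes on the array 6491 were tested, 5948 with NCU identifiers, 519 clone-coded and 24 mitochondrial, and 93 had a missing value.

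One limma model over all 16 arrays held 4 coefficients, the log2 ratio and a gene-wise dye effect for each comparison, with 12 residual and 3.888 prior degrees of freedom. Tests were two-sided moderated t tests with Benjamini-Hochberg adjustment, and a call is adjusted p under 0.05. The indirect contrast is the sum of both log2 ratios, and its SE comes from the same model. Gene lists, 26 in all, were fixed before the data were examined, from symbols that name the function. No product annotation was used, so genes without such a symbol or a chosen identifier are missing from the lists. Lists with at least 4 measured genes were tested with cameraPR (preset correlation 0.01) and adjusted over the 19 tested, and camera with an estimated correlation and fry were alternatives. List values give genes called over all genes unless adjusted over the list alone. Some members that do not belong by function were dropped before any list value was read, among them the mitochondrial *cyt* factors and the glycosyl hydrolases of the fungal wall. Membership otherwise rests on the symbol or identifier, so other members of this kind may remain.

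The genes named are *mak-2* and all measured genes of both phosphorus lists, then per comparison and direction the 10 largest changes with a symbol among genes called, of one sign and above background on all 8 arrays. To these came the 2 largest per direction whatever the name under the same conditions, and per list up to 2 called members with the largest rise and 2 with the largest fall. This gave 82 and 81 names. Both the rule and the alternatives were set before the data were examined, and 4 alternatives were added after seeing the data. These 4 are the median of foreground pixels, the rows read 1 position off left out, the 2 arrays that stood apart left out, and scan day 5 alone. The last kept only the 3 WT arrays of that day, in a joint fit with all *mak-2* arrays. The 2 arrays that stood apart were number 2 with low Pi RNA in Cy5 and number 1 with *mak-2* RNA in Cy5.

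Pairing was checked from the data, by correlating residuals of opposite-dye arrays across genes. In the WT comparison arrays with one number had r of 0.143 to 0.525, other pairs −0.518 to 0.493, and 3 of 4 arrays fitted best with their own number. Number 3 with low Pi RNA in Cy3 fitted best with number 1 (0.493, against 0.143 with its own). Pairing by number is thus likely but not shown, and the main fit has no block for it. In the *mak-2* comparison the values were −0.583 to 0.382 and −0.667 to 0.681, with 1 of 4 best with its own, so no pairing by number showed there. Log2 ratios of arrays correlated across genes at 0.634 to 0.944 within a dye orientation and 0.490 to 0.877 between orientations in the WT comparison, and at 0.592 to 0.938 and 0.518 to 0.896 in the *mak-2* one. The scans fell on 5 days. In the *mak-2* comparison the day coincided with the dye orientation, and every array carried both RNAs.

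The scanner grid was checked by correlating each spot row with the same row on other arrays of its group, in place and shifted by 1 position. Rows counted as misread where the shifted correlation reached 0.6 and gained 0.1, limits set after seeing the screen. Of 9216 rows 8 met this, on 4 arrays, with 160 spots.

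The steps were tested on simulated data with known changes in 200 genes. At true log2 changes of 0.5, 1 and 2 the recovery was 56.9, 91.3 and 100% for the WT comparison, 64.4, 89.6 and 100% for *mak-2* and 28.6, 80.7 and 98.7% for the indirect contrast. The false share among calls was 7.96, 1.56 and 3.15%. Values were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, tests were run with R 4.3.3, limma 3.58.1 and statmod 1.5.0, and plots were drawn with matplotlib 3.10.9.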

Results

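The data were 16 two-colour arrays of *Neurospora crassa* RNA, read from the deposited scanner files. Per the labels, mycelia of the wild type (WT) and of the *mak-2* deletion strain grew for 5 h at 30 °C in medium with low (10 µM) or high (15 mM) inorganic phosphate (Pi). Of these arrays, 8 carried WT low Pi RNA beside WT high Pi RNA and 8 carried *mak-2* RNA beside WT RNA, both at low Pi. In each comparison 4 arrays held the numerator RNA in Cy3 and 4 held it in Cy5. Between 44.1 and 73.5% of gene probes stood above the local background in at least 1 channel (median 60.3%). By channel, 4431 to 7450 gene probes did so in Cy5 and 954 to 6483 in Cy3. On the 4 arrays with *mak-2* RNA in Cy5, Cy3 held WT RNA and had 954, 2179, 4357 and 3539 such probes. Many ratios on these arrays, above all on the first 2, thus rest on an undetected WT signal. The tests covered 6491 genes, of which 914 had a gene symbol. The number of arrays limits the precision of each ratio. The labels do not say which arrays shared an RNA extract, so the p-values measure spread between these arrays, which may be technical.

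The first comparison asked which transcripts WT changed at low Pi. All log2 values here are low over high Pi, the opposite sign to the deposited value table. All 3 measured phosphorus acquisition genes rose. The alkaline phosphatase gene *pho-2* (NCU01376) rose by 6.28 ± 0.60 (SE of the limma fit), 77.7-fold, with limma adjusted p = 1.74e-07 and a rise on 7 of 8 arrays. The phosphate permease gene *pho-5* (NCU08325) rose by 5.34 ± 0.13, 40.4-fold, on all 8 arrays (adjusted p = 1.52e-14). The permease gene *pho-4* (NCU09564) rose at least 22.2-fold (log2 4.47 ± 0.08, adjusted p = 8.45e-16, all 8 arrays), a bound for the fitted value only, given because its low Pi signal was saturated on all 8 arrays. *pho-2* read −0.29 on 1 array, with low Pi RNA in Cy3, and without the misread rows its change was 7.23. Its high Pi signal was above background on 4 of 8 arrays.

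None of the 3 measured regulators of this pathway passed the test. The activator gene *nuc-1* (NCU09315) had −0.38 ± 0.18 (adjusted p = 0.1), *preg* (NCU01738) −0.19 ± 0.16 (adjusted p = 0.358) and *mdk-1* (NCU07580) 0.07 ± 0.25 (adjusted p = 0.846). *nuc-1* passed the threshold with print-tip loess, at −0.46, and with this comparison fitted on its own arrays. *pho-3* and *nuc-2* had no probe under their identifiers. *mak-2* itself (NCU02393) had −0.12 ± 0.26 (adjusted p = 0.744), with a ratio below 0 on 2 of 8 arrays. One array with low Pi RNA in Cy5 read −2.01, and without it the value turned to 0.12.

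Other large rises at low Pi included genes for a hydrophobin, a potassium transporter and a catalase. The hydrophobin gene *eas* (NCU08457) rose by 4.76 ± 0.13, at saturation in low Pi RNA on 5 of 8 arrays, the glycosyl hydrolase family 18 gene *gh18-8* (NCU07484) by 4.81 ± 0.14 and *ccg-1* (NCU03753) by 4.17 ± 0.16. The potassium transporter gene *hak-1* (NCU00790) rose by 3.63 ± 0.08, *gh31-3* (NCU04674) by 2.92 ± 0.09, the catalase gene *cat-2* (NCU05770) by 2.61 ± 0.11, *gdh-1* (NCU00461) by 2.53 ± 0.10 and *con-8* (NCU09235) by 2.42 ± 0.11. Each of these 8 genes rose on all 8 arrays, with adjusted p of 2.12e-11 or below. *gh18-8* was above background in high Pi RNA on 1 of 8 arrays, and *con-8* stood at 1.51 with the mean of its probes. Among genes of one sign and above background on all 8 arrays, the largest rises whatever the name were in 2 probes. These were the clone-coded probe 4nc671_010, by 6.44 ± 0.17, and NCU09210, by 5.40 ± 0.18 (6.71 with plain background subtraction). *pho-2*, at 6.28, was outside this ranking because 1 array read below 0.

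The largest falls included an amino acid permease gene and several ribosomal protein genes. The amino acid permease gene *mtr* (NCU06619) fell to a log2 ratio of −3.65 ± 0.15, *un-25* (NCU05554) to −3.57 ± 0.19, *crp-5* (NCU04552) to −3.23 ± 0.13, *cpc-2* (NCU05810) to −3.22 ± 0.11, *rap-1* (NCU03393) to −3.22 ± 0.23 and *crp-3* (NCU07014) to −3.19 ± 0.12. *crp-4* (NCU04331) stood at −3.09 ± 0.29 (−3.77 on the arrays of scan day 5), *un-16* (NCU01949) at −3.05 ± 0.11, *cyh-2* (NCU03806) at −3.0 ± 0.09 and *crp-15* (NCU00258) at −2.87 ± 0.12. Each of these 10 genes fell on all 8 arrays, with adjusted p of 1.49e-07 or below. Under the same conditions, the largest falls whatever the name were in NCU01546, at −4.01 ± 0.22 (−1.99 with the mean of its probes), and NCU05338, at −3.69 ± 0.12. NCU01546 had 2 probes, and the dimmer one read 0.04, so the fall was not seen by both.

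Across all genes, 3083 of 6491 (47.5%) changed, 1514 up and 1569 down (1701 and 1264 under median centring), and 848 of them by at least 2-fold, 399 up and 449 down. Of the 3083, 2148 had the same sign on all 8 arrays. With the replicate number as a block 2919 genes were called, and 2780 with arrays of one number averaged. With the scan day as a block 3068 were called, and 2017 when only the 3 WT arrays of scan day 5 were kept, 1 with low Pi RNA in Cy3 and 2 with it in Cy5, so that most of the spread came from the *mak-2* arrays of the joint fit.

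Among gene lists fixed before the data were examined, 8 of the 19 tested passed the camera test at low Pi, 4 up and 4 down. All 7 measured genes of the cytosolic ribosomal protein list, those with a *crp* symbol, fell (median −2.87, adjusted p = 2.3e-07), among them *crp-5* and *crp-3*. In amino acid biosynthesis 46 of 58 genes fell and 4 rose (median −1.10, adjusted p = 1.31e-13), with 51 called when adjusted over the list alone. The falls included *cpc-2* and *hom-1* (NCU00554, −2.76), while *ilv-5* (NCU02397, 2.10) and *cys-18* (NCU07930, 1.26) rose. In glycolysis and fermentation 5 of 6 fell (median −0.79, adjusted p = 0.00773, adjusted p = 0.086 with an estimated correlation), led by *cfp* (NCU02193, −1.95, high Pi signal saturated on 5 of 8 arrays) and *emp-6* (NCU02252, −1.17). In phospholipid and sterol synthesis 5 of 7 fell (median −0.54, adjusted p = 0.00551, adjusted p = 0.0918 with an estimated correlation), and 7 when adjusted over the list alone, led by the inositol phosphate synthase gene *inl* (NCU06666, −2.72) and *erg-1* (NCU04156, −1.35).

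In conidiation and clock output 10 of 16 genes rose and 1 fell (median 0.69, adjusted p = 0.000462, adjusted p = 0.0658 with an estimated correlation). The one that fell was *ccg-14* (NCU07787, −1.13). In fungal cell wall synthesis 11 of 23 rose and 3 fell (median 0.31, adjusted p = 0.0213, adjusted p = 0.386 with an estimated correlation, lost under median centring at 0.076). *acw-6* (NCU03530, 1.85) and *acw-12* (NCU08171, 1.74) rose there, and *acw-4* (NCU09263, −1.35) and *acw-5* (NCU07776, −0.89) fell. Oxidative stress had 5 of 8 genes up and 1 down (median 0.47, adjusted p = 0.0389, adjusted p = 0.3 with an estimated correlation), with *cat-2* and *gst-1* (NCU05780, 1.14) up and *cat-4* (NCU05169, −0.39) down. Plant cell wall degradation had 9 of 26 up and 3 down (median 0.27, adjusted p = 0.0459, adjusted p = 0.3 with an estimated correlation), with *gh31-3* and *gla-1* (NCU01517, 1.76) up and *gh61-2* (NCU07760, −0.78) and *gh28-1* (NCU02369, −0.49) down. These last 2 calls were lost with print-tip loess, at 0.0892 for each, and with several other settings.

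The other 11 lists tested at low Pi did not pass. In the carotenoid and light list 5 of 9 genes rose, *al-1* (NCU00552, 1.81) and *al-3* (NCU01427, 0.94) the most, and *frq* (NCU02265) fell at least 1.61-fold in the loess-normalized values, its low Pi signal being below background on all 8 arrays (list median 0.64, adjusted p = 0.0808). The *frq* call was lost with array weights, at −0.44, a smaller fall than that bound. Of 10 MAP kinase cascade genes *os-2* (NCU07024, 1.10) and *os-5* (NCU00587, 0.45) rose. *mek-1* (NCU06419, −0.25, adjusted p = 0.0381) fell by a call that averaging of arrays with one number ended. The median of the MAP kinase list was −0.09, its mean 0.05 and its test upward (adjusted p = 0.949), and median centring turned its median to 0.04. In cell fusion 3 of 14 rose, with *hex-1* (NCU08332, 0.89, saturated in low Pi RNA on 6 of 8 arrays) and *pp-1* (NCU00340, 0.64) first, and 3 fell, with *ham-10* (NCU02833, −1.11) and *Prm1* (NCU09337, −1.07) first. The cell fusion median was −0.08 (adjusted p = 0.949), and median centring turned it to 0.04. In mating 2 of 5 rose, *Asm-1* (NCU01414, 0.34) and *sub-1* (NCU01154, 0.33, a call that averaging of arrays with one number ended). The mating median was −0.12, its mean 0.04 and its test upward (adjusted p = 0.949), and print-tip loess turned its median to 0.01.

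The respiratory chain had 4 of 31 genes up, *nuo6.6* (NCU00160, 0.55) and *nuo51* (NCU04044, 0.42) first, and 8 down, *cox-4* (NCU05689, −0.91) and *cox-6* (NCU06695, −0.91) first (median −0.08, adjusted p = 0.35). The citrate and glyoxylate list had *acu-9* (NCU10007, 1.46) and *acu-15* (NCU06656, 0.89) up and *cit-1* (NCU01692, −0.79) and *acu-8* (NCU09770, −0.32) down. Its median was −0.07, its mean 0.18 and its test upward (adjusted p = 0.949). In the vacuolar list 4 of 14 rose, *vma-10* (NCU05118, 0.56) and *vma-2* (NCU08515, 0.49) first (median 0.11, adjusted p = 0.218). Heat shock genes split, with *hsp98* (NCU00104, 0.57) and *grp78* (NCU03982, 0.53) up and *hsp60* (NCU01589, −1.76) and *hsp70-2* (NCU02075, −1.71) down (median −0.29, adjusted p = 0.581). Of 29 proteasome genes 4 rose, *pcb-1* (NCU09290, 0.56) and *pcb-3* (NCU03304, 0.43) first, and *pca-2* (NCU06764, −0.37) fell. The proteasome median was −0.03 and its test upward (adjusted p = 0.949), and median centring turned the median to 0.09. Among histones *hH2A* (NCU02437, 0.38) and *hH3v* (NCU00145, 0.30) rose and *hH2Az* (NCU05347, −0.88) and *hH3* (NCU01635, −0.42) fell. The histone median was −0.04 (adjusted p = 0.986) and 0.05 with the deposited value table. In secondary metabolism *pks-3* (NCU04865, 0.29) rose and *pks-6* (NCU02918, −0.51) fell (median −0.20, adjusted p = 0.949). The calls of *mek-1*, *sub-1*, *pks-6* and *frq* weakened in 17, 13, 10 and 6 alternatives, and those of *Asm-1* and *pca-2* in 5. The 3 phosphorus acquisition genes, the 3 phosphorus signalling genes and the 1 sugar transport gene, *hgt-1* (NCU10021, 1.46), were too few for a list test. No gene was matched by symbol for ribosome biogenesis, for translation factors and tRNA synthetases, for mitochondrial ribosomal proteins or for nucleases and nucleotide salvage.

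**Figure D1:**
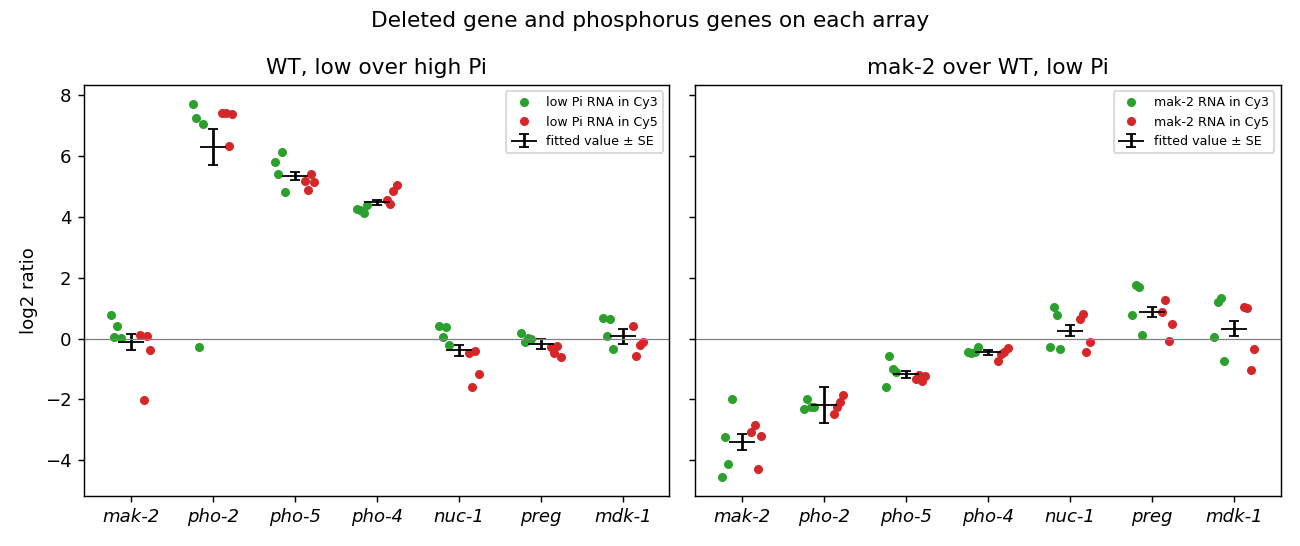
Log2 ratio on each array (vertical axis) for mak-2, pho-2, pho-5, pho-4, nuc-1, preg and mdk-1 in both comparisons, 8 arrays each, green points with the numerator RNA in Cy3, red points with it in Cy5, and black marks for the fitted value ± SE. pho-2, pho-5 and pho-4 rose at low Pi (6.28, 5.34 and 4.47) and were lower in mak-2 than in WT (−2.18, −1.18 and −0.45), the last turning to 0.16 under median centring.

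The second comparison asked what the *mak-2* deletion changed at low Pi. The *mak-2* probe (NCU02393) fell to a log2 ratio of −3.41 ± 0.26, 10.6-fold lower, on all 8 arrays (−4.55 to −2.0, limma adjusted p = 1.31e-08), and to −4.84 with plain background subtraction. It was above background in *mak-2* RNA on 2 of 8 arrays and in WT RNA on 5 of 8. All 3 measured phosphorus acquisition genes were lower in *mak-2*. *pho-2* (NCU01376) fell to −2.18 ± 0.60 (adjusted p = 0.0053), *pho-5* (NCU08325) to −1.18 ± 0.13, 2.26-fold lower (adjusted p = 8.1e-07), and *pho-4* (NCU09564) to −0.45 ± 0.08 (adjusted p = 0.000167), each on all 8 arrays.

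The *pho-5* fall was smaller, −0.71, with print-tip loess and with median centring. The *pho-2* call was lost with array weights, at −2.08. The 4 arrays with *mak-2* in Cy3 read from −2.30 to −1.99. The SE of *pho-2* comes from the joint fit, so it also holds the spread of the WT arrays, 1 of which read −0.29. With the 4 arrays of *mak-2* in Cy5 left out and the dye term taken from the WT arrays, which hold the reading of −0.29, *pho-2* had −1.35 and was not called. The *pho-4* signal was saturated in WT on 7 of 8 arrays and in *mak-2* on 5 of 8, and median centring reversed its value to 0.16. *preg* (NCU01738) rose by 0.87 ± 0.16 (adjusted p = 0.000282, 7 of 8 arrays, WT signal above background on 2 of 8). *mdk-1* (NCU07580) had 0.32 ± 0.25 (adjusted p = 0.284) and *nuc-1* (NCU09315) 0.26 ± 0.18 (adjusted p = 0.238), which turned to −0.23 in 1 alternative. One label of the 4 arrays with *mak-2* in Cy5 names high Pi for the WT channel against their titles. On those 4 arrays *pho-2* read from −2.48 to −1.84, close to the arrays of *mak-2* in Cy3, and *pho-5* and *pho-4* were also below 0. In WT these 3 genes rose at low over high Pi, by 6.28, 5.34 and 4.47. Their values argue against a high Pi WT channel there, as far as these genes go. Without those 4 arrays and with the dye term of the WT arrays, 2452 genes were called.

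The largest rises in *mak-2* included many of the genes with the largest falls at low Pi. *un-25* (NCU05554) rose by 3.55 ± 0.19, *rap-1* (NCU03393) by 3.54 ± 0.23, *cpc-2* (NCU05810) by 3.12 ± 0.11, *crp-10* (NCU00489) by 3.09 ± 0.36, *crp-4* (NCU04331) by 3.07 ± 0.29 and *crp-5* (NCU04552) by 2.99 ± 0.13. *crp-3* (NCU07014) and *crp-15* (NCU00258) rose by 2.75 ± 0.12 each and *un-16* (NCU01949) by 2.66 ± 0.11. The conidiation gene *con-10* (NCU07325) rose by 2.83 ± 0.13, and it had also risen at low Pi, by 1.57. Under the same conditions as at low Pi, NCU07201 had the largest rise whatever the name, 4.13 ± 0.19, with WT signal above background on 2 of 8 arrays. All 11 of these genes rose on all 8 arrays, with adjusted p of 1.58e-06 or below.

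The largest falls included the hydrophobin gene and 3 cell wall genes. *eas* (NCU08457) fell to a log2 ratio of −5.26 ± 0.13 (a value limited by saturation in WT on 7 of 8 arrays), *gh18-8* (NCU07484) to −5.07 ± 0.14 and *hak-1* (NCU00790) to −4.71 ± 0.08. The wall genes *ncw-1* (NCU05137), *ncw-3* (NCU07817) and *acw-12* (NCU08171) fell to −4.49 ± 0.37, −3.71 ± 0.11 and −3.52 ± 0.11, the first to −5.75 with plain background subtraction. *con-8* (NCU09235) fell to −3.77 ± 0.11 (−2.20 with the mean of its probes), *ccg-1* (NCU03753) to −3.23 ± 0.16, *cfp* (NCU02193) to −2.83 ± 0.16, *ada-1* (NCU00499) to −2.66 ± 0.10 and *cat-2* (NCU05770) to −2.63 ± 0.11. The alcohol dehydrogenase gene *adh-1* (NCU01754) fell to −2.55 ± 0.12, and it had also fallen at low Pi. Under the same conditions, the largest falls whatever the name were in the clone-coded probe 1nc397_010, at −6.83 ± 0.14, and in NCU05134, at −5.87 ± 0.32. All 14 genes fell on all 8 arrays, with adjusted p of 2.81e-08 or below.

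Across all genes, 3691 (56.9%) differed between *mak-2* and WT, 1974 up and 1717 down (2312 and 1375 under median centring), and 978 of them by at least 2-fold, 460 up and 518 down. Of the 3691, 2229 had the same sign on all 8 arrays, and 3663 were called with the scan day as a block.

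Of the 19 lists tested, 9 passed in *mak-2*, 5 up and 4 down. All 7 genes of the cytosolic ribosomal protein list rose (median 2.75, adjusted p = 2.45e-06), with *crp-10* and *crp-4* first. In amino acid biosynthesis 39 of 58 rose and 4 fell (median 0.89, adjusted p = 2.21e-08), and 45 were called when adjusted over the list alone. *cpc-2* and *leu-2* (NCU04385, 2.01) led the rises, and *met-6* (NCU00892, −1.99, −1.24 with the median of foreground pixels) and *cys-18* (NCU07930, −0.72) fell. All 7 phospholipid and sterol genes rose (median 0.31, adjusted p = 0.0107, adjusted p = 0.146 with an estimated correlation), with *inl* (NCU06666, 2.38) and *erg-4* (NCU03006, 1.49) first. In heat shock and chaperones 7 of 10 rose, *hsp60* (NCU01589, 1.89) and *hsp70-2* (NCU02075, 1.48) first, and *hsp98* (NCU00104, −0.72) fell (median 0.89, adjusted p = 0.0214, adjusted p = 0.168 with an estimated correlation). In the proteasome 17 of 29 rose and none fell (median 0.33, adjusted p = 0.0305, adjusted p = 0.414 with an estimated correlation), with *rpn-8* (NCU01547, 1.12) and *rpt-3* (NCU02260, 1.02) first. These last 2 list calls were lost when only genes above background on all 16 arrays were kept, the heat shock call also without the arrays of *mak-2* in Cy5 and the proteasome call also without 1 of the arrays of *mak-2* in Cy3.

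Among the 4 lists that fell, the respiratory chain had the smallest adjusted p, with 21 of 31 genes down and 6 up (median −0.97, adjusted p = 3e-06). All 21 falls were among its 26 *nuo* genes of complex I. The 5 other members rose. The genes *nuo6.6* (NCU00160, −2.28) and *nuo21.3c* (NCU05009, −1.73) fell the most, while *cox-6* (NCU06695, 0.77) and *cox-4* (NCU05689, 0.66) had the largest rises. In conidiation and clock output 11 of 16 fell, *eas* and *con-8* first, and *con-10* and *acon-3* (NCU07617, 0.55) rose (median −1.0, adjusted p = 2e-04). In fungal cell wall synthesis 13 of 23 fell, *ncw-1* and *ncw-3* first, and 3 rose, *acw-5* (NCU07776, 1.01) and *gel-4* (NCU07253, 0.74) first (median −0.69, adjusted p = 0.000307, adjusted p = 0.168 with an estimated correlation). In cell fusion 6 of 14 fell and *ham-3* (NCU08741, 0.88) rose (median −0.37, adjusted p = 0.0301, adjusted p = 0.304 with an estimated correlation). The members of this list that fell the most were *hex-1* (NCU08332, −1.91, saturated in WT on 6 of 8 arrays) and *Prm1* (NCU09337, −1.54, −2.30 with plain background subtraction). The transcription factor gene *pp-1* (NCU00340, −1.31) fell too. Median centring moved the medians of the phospholipid, proteasome, respiratory, fungal wall and cell fusion lists to 0.69, 0.62, −0.61, −0.45 and −0.19.

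The other 10 lists did not pass in *mak-2*. Of 10 MAP kinase cascade genes 4 fell, *mak-2* and *mek-1* (NCU06419, −1.10) first (median −0.15, adjusted p = 0.107). In mating the pheromone receptor gene *pre-2* (NCU05758) rose by 2.41 ± 0.16, *fmf-1* (NCU09387) rose at least 2.11-fold with WT signal below background on all 8 arrays, and *Asm-1* (NCU01414, −1.24) fell. The mating median was −0.17, its mean 0.48 and its test upward (adjusted p = 0.817). In the carotenoid and light list *frq* (NCU02265, 0.58) rose and *al-1* (NCU00552, −0.61) and *nop-1* (NCU10055, −0.48) fell. Its median was 0.07, its mean −0.07 and its test downward (adjusted p = 0.589), and print-tip loess turned its median to −0.03. Glycolysis had *emp-1* (NCU02542, 0.43) and *emp-6* (NCU02252, 0.31, a call lost with print-tip loess and without the arrays of *mak-2* in Cy5) up and *cfp* and *gpd-1* (NCU01528, at least 1.75-fold lower in the loess-normalized values, saturated in WT on all 8 arrays, −0.21 and not called under median centring) down. The glycolysis median was −0.05 (adjusted p = 0.589) and turned to 0.42 under median centring. The citrate list had *acu-8* (NCU09770, 1.36) and *cit-1* (NCU01692, 1.25) first of 3 genes up and *acu-15* (NCU06656, −0.36, adjusted p = 0.0452, weaker in 22 alternatives) down (median 0.92, adjusted p = 0.0791).

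In the vacuolar list *vma-5* (NCU09897, 0.81) rose and *vma-10* (NCU05118, −0.62) and *vma-2* (NCU08515, −0.55) led 3 falls, both lost under median centring. The vacuolar median was −0.06 (adjusted p = 0.589) and turned to 0.19 under median centring. In oxidative stress *gst-3* (NCU01320, 0.94) and *cat-4* (NCU05169, 0.25, adjusted p = 0.0496, weaker in 27 alternatives) rose and *cat-2* and *cat-3* (NCU00355, −1.34) led 3 falls. The oxidative stress median was −0.16 (adjusted p = 0.321) and turned to 0.02 under median centring. In plant cell wall degradation 6 of 26 rose, *inv* (NCU04265, 1.34) and *gh3-3* (NCU08755, 0.92) first, and 8 fell, *gla-1* (NCU01517, −2.38) and *gh3-6* (NCU07487, −1.69) first (median −0.09, adjusted p = 0.245). Of 8 histones 3 rose, *hH2Az* (NCU05347, 0.94) and *hH4-1* (NCU01634, 0.50) first (median 0.23, adjusted p = 0.495), with 6 up and median 0.51 under median centring and 1 up and 1 down with the deposited value table. In secondary metabolism *pks-6* (NCU02918, 1.29) and *pks-2* (NCU05011, 0.52) rose and *pks-4* (NCU08399, −0.46) fell (median 0.19, adjusted p = 0.739). *hgt-1* (NCU10021, −0.64) fell. The calls of *frq*, *acon-3*, *hH4-1* and *gel-4* weakened in 16, 10, 9 and 8 alternatives, and those of *cys-18* and *hgt-1* in 7.

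The third comparison asked how *mak-2* at low Pi stood against WT at high Pi, an indirect contrast that adds both log2 ratios. The 3 phosphorus acquisition genes stayed high, with *pho-2* (NCU01376) at 4.10 (adjusted p = 0.00159), *pho-5* (NCU08325) at 4.16 (adjusted p = 6.06e-11) and *pho-4* (NCU09564) at 4.02 (adjusted p = 3.56e-13), the last limited by saturation at low Pi in WT on all 8 arrays of the first comparison and in *mak-2* on 5 of 8. The *pho-2* sum includes the WT array that read −0.29. Without the misread rows its Pi change was 7.23 instead of 6.28, so 4.10 is likely too low. *con-10* (NCU07325) stood at 4.40 and *adh-1* (NCU01754) at −5.10, *preg* (NCU01738) rose by 0.67 (adjusted p = 0.0405), and *mak-2* (NCU02393) stood at −3.53. Here 1773 genes (27.3%) changed, 908 up and 865 down, and 525 by at least 2-fold, 208 up and 317 down. Median centring moved the share of higher calls from 51.2 to 74.0% and the median of all genes from 0.02 to 0.20.

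Of the lists 7 passed, 2 up and 5 down. In the respiratory chain 22 of 31 genes, all 22 of them *nuo* genes, fell and none rose (median −1.06, adjusted p = 1.62e-14), with 17 down and median −0.70 under median centring. Glycolysis fell (5 of 6 genes, median −0.86, mean −1.36, adjusted p = 0.000755, with 2 genes down and median −0.44 under median centring) and the citrate and glyoxylate list rose (4 of 6, median 0.82, adjusted p = 0.00175). Cell fusion fell (6 of 14, median −0.52, adjusted p = 0.00175, adjusted p = 0.215 with an estimated correlation, median −0.23 under median centring), as did amino acid biosynthesis (23 of 58, with 4 up, median −0.31, adjusted p = 0.00339, adjusted p = 0.216 with an estimated correlation). Under median centring amino acid biosynthesis had 7 genes up and 8 down, with median −0.02. The proteasome rose (5 of 29, median 0.26, adjusted p = 0.00702, adjusted p = 0.347 with an estimated correlation), with 17 genes up and median 0.68 under median centring. Fungal cell wall synthesis fell (6 of 23, with 1 up, median −0.15, adjusted p = 0.021, adjusted p = 0.378 with an estimated correlation), and its median turned to 0.26 under median centring. Of the 7 genes of the cytosolic ribosomal protein list 1 fell (median −0.13, adjusted p = 0.42), and median centring turned that median to 0.34.

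**Figure D2:**
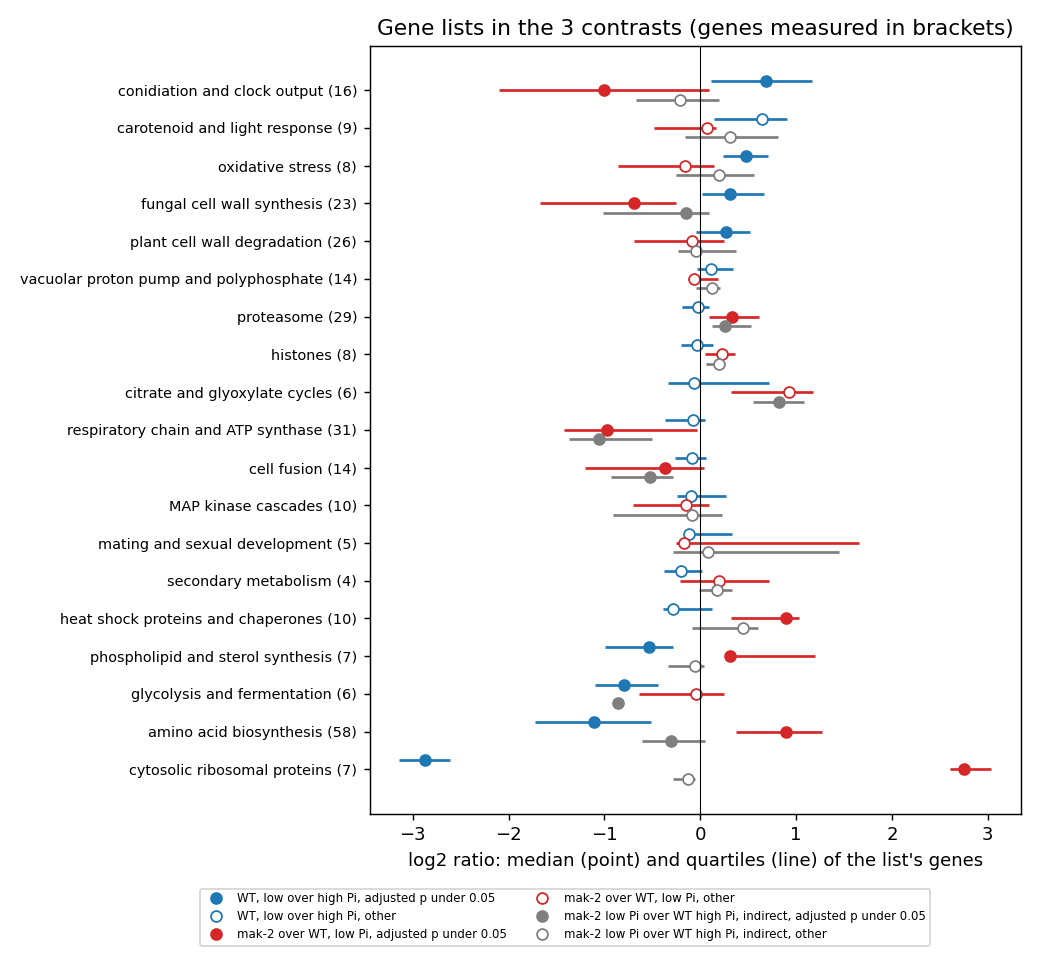
Median log2 ratio (points) and quartiles (lines) of the genes in each of the 19 tested lists, for WT low over high Pi (blue), mak-2 over WT at low Pi (red) and the indirect contrast (grey), filled where adjusted p was under 0.05, with the genes measured in brackets. The ribosomal protein list fell at low Pi (−2.87) and rose in mak-2 (2.75). The respiratory chain list, whose falls were all in complex I genes, fell in mak-2 (−0.97), with −0.08 at low Pi. Some open or grey medians near 0, among them the indirect fungal cell wall one, turned sign under median centring.

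The last question was how the *mak-2* effect related to the Pi response, gene by gene. Of 2257 genes called in both comparisons, 1987 (88.0%) moved in opposite directions and 270 in the same one. Independent lists would share 400.5 genes higher at low Pi and lower in *mak-2* (971 observed) and 477.2 of the reverse (1016 observed). *eas*, *gh18-8*, *hak-1*, *ccg-1*, *cat-2* and *con-8* rose at low Pi and fell in *mak-2*, and *un-25*, *rap-1*, *cpc-2*, *crp-5*, *crp-3* and *un-16* did the reverse. *con-10* rose in both and *adh-1* and *cfp* fell in both. Across all 6491 genes the log2 ratios had r = −0.657, a correlation across genes, which are not independent replicates. Both ratios hold WT low Pi RNA with opposite signs, and simulations with shared extracts and no effect gave r = −0.494 to −0.665. The covariance was −0.442 against −0.0134 to −0.0266 in those simulations, and −0.465 and −0.405 with the array numbers divided between the comparisons. The simulations used the residual spread between arrays, which may leave out differences between extracts. Of the genes changed by at least 2-fold at low Pi, 691 of 848 (81.5%) were called in the opposite direction in *mak-2*. Another 826 genes were called at low Pi only and 1434 in *mak-2* only. Of the genes moved in opposite directions, 1485 (74.7%) were not called in the indirect contrast, 263 were called toward the Pi response and 239 toward the *mak-2* effect. That contrast called 27.3% of all genes.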

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

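All tests of the opposite movement were chosen only after the result was seen, while the tests of the *pho-2* spot, of neighbouring genes and of the array splits were written down before their values were read.

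The opposite movement of the Pi response and the *mak-2* effect may have come from chance values of WT low Pi extracts shared by both comparisons, from 1 unusual WT low Pi culture or RNA pool behind all 16 arrays, or from a low Pi transcript state that needs MAK-2. Shared extracts that differ only by the residual spread between arrays did not give it in simulations. The covariance across genes was −0.442, which is 16.6 times the largest one simulated in this way (−0.0266), although those simulations reached a correlation of −0.665. If the arrays are technical replicates, that spread leaves out differences between extracts, so shared extracts were not excluded. Of the genes moved in opposite directions 74.7% were not called in the indirect contrast, which called 27.3% of all genes. Ratios of opposite sign partly cancel in that sum, so this share tells nothing about the cause. The median ratio of the *mak-2* effect to the Pi response among the 848 genes changed at least 2-fold at low Pi was −0.779, with quartiles −1.01 and −0.395. An unusual pool and a need for MAK-2 cannot be told apart with these values, because both give ratios near −1 and the arrays hold no *mak-2* RNA from high Pi and no WT low Pi RNA known to come from another culture. A need for MAK-2 remains a hypothesis, and of those 848 genes 398 were still called in the indirect contrast, 349 of them in the direction of the Pi response.

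The *pho-2* ratio of −0.29 on the third array with low Pi RNA in Cy3, against 7.03 to 7.71 on the others of its group, may come from the scanner software's grid being off the spots in that row. The row correlated with the same row on the other arrays at 0.26 in its own position and at 0.906 shifted by 1 position, while other rows of its block had 0.886 or more. This is consistent with a misread row, and without such rows the *pho-2* change was 7.23.

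Neighbouring genes changed together more often than shuffled positions gave, which may reflect chromosome regions or, as a technical explanation, probes of neighbours printed in the same block. In different print blocks 68 of 3730 pairs changed the same way by at least 2-fold at low Pi (shuffled mean 31, highest 46, permutation p = 0.001, the smallest possible with 1000 shuffles). Only 7 of 3737 pairs shared a block, so a shared block cannot account for it. The *mak-2* comparison also had 68 such pairs (highest shuffled 56). The longest run had 4 genes, *gh18-8*, NCU07485, NCU07486 and *gh3-6*, printed in blocks 20, 24, 28 and 32. The blocks followed the gene order there, so other effects of the print layout were not excluded. Whether regions, shared functions of neighbours or the print layout account for it was not tested.

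With all arrays divided freely, 1 of 35 splits, the real one, called as many genes in the WT comparison (3083, highest other 0). It was 1 of 35 in *mak-2* (3691, highest other 1) and 1 of 100 in the indirect contrast (1773, highest other 0), each a share under 0.05. The other splits turn the sign of some arrays, so few calls are due there for any RNAs that differ. The splits divide arrays and not cultures, so chance differences between single cultures were not excluded. If the WT arrays are paired by number, the 8 splits that part all of their pairs (3083, highest other 0) are too few for a share under 0.05. For the list counts chance was not excluded, with 4 of 35 splits calling as many lists in the WT comparison (8, highest other 8) and 4 of 35 in *mak-2* (9, highest other 9). The 3 other splits in each keep 6 of 8 arrays as in the real one and so still carry its effect, while the 18 splits that keep 4 called at most 2 lists in the WT comparison and 3 in *mak-2*.

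Of 346 groups of 4 values, 18 held a value far from the other 3, where 17.3 are due at 1 in 20. In the WT arrays with low Pi RNA in Cy3 these were, besides *pho-2*, *un-25* −3.77, *acu-8* −0.07, *vma-10* 0.90 and *hH2A* 0.60. With low Pi RNA in Cy5 they were *pho-2* 6.33, *gh18-8* 5.41, 4nc671_010 5.02, *mek-1* −1.03, *vma-2* 0.28, *gh61-2* −1.39 and *hgt-1* −0.16. With *mak-2* RNA in Cy3 they were *adh-1* −3.35 and *hsp98* −0.23, and with it in Cy5 *ncw-3* −2.95, *cat-2* −3.29, *cat-4* 0.48 and *pks-2* 0.31. The probes for the hygromycin resistance gene *hph*, the marker used in *Neurospora* knockout strains, had 2.16 ± 0.43 (SD, hph_pCSN44) and 2.10 ± 0.79 (SD, hph_pCSN44_half) in *mak-2* over WT, above 0 on all 8 arrays (exact sign-flip p = 0.0078 for each, adjusted p = 0.125 over 56 tests). They stood above background in *mak-2* RNA on 8 and 7 of 8 arrays and in WT RNA on 0. With WT undetected these values are not exact differences, and no bound was computed for these probes. None of 163 named results had all 4 ratios above 0 in one dye orientation and all 4 below 0 in the other. The naming rule asked for a call or for 1 sign on all 8 arrays in most of them, so this tells little about dye effects.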

How the results depend on the processing

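The 4 added tests with other foreground values, misread rows, doubted arrays or 1 scan day were chosen only after the results were seen, and all others before the data were examined. Over all alternatives the WT count ran from 848 to 3733, the *mak-2* count from 978 to 4152, the indirect count from 525 to 2582 and the opposite overlap from 475 to 2371. Of 6316 named gene values 6065 kept their sign and call, 240 kept the sign and lost the call, and 2 gained a call. Another 8 changed sign without a call and 1 reversed. Some alternatives could hardly move a value, which raises the number kept. Equalizing the brightness between arrays (Aquantile) gave the same counts as the main fit. Leaving out an array of the other comparison changes only the spread. Size was not part of the count of kept values, and NCU01546 at low Pi stood at −1.99 with the mean of its probes against −4.01. Its dimmer probe read 0.04. The deleted gene stood above background in *mak-2* RNA on 2 of 8 arrays and had −4.84 with plain subtraction and no offset against −3.41, so with such low signal over background its fold is only approximate. The cause of the changed counts was not tested.

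Median centring called 5 WT lists and reversed *pho-4* in *mak-2* to 0.16. Keeping only the 2482 genes above background on all 16 arrays gave 1568, 1696 and 1004 calls, an overlap of 1074 and r = −0.751 across genes. Adjusted p under 0.01 gave 1110 indirect calls. A 2-fold change gave 848, 978 and 525 calls and an overlap of 475. Without the arrays of *mak-2* in Cy5, and with the dye term of the WT arrays, 2452 genes were called. With only the 3 WT arrays of scan day 5 kept beside all *mak-2* arrays, which then supply most of the spread, there were 2017 WT calls and an overlap of 1311. Camera with an estimated correlation called 2 WT and 4 *mak-2* lists, and fry called 17 *mak-2* lists. The 2 doubted arrays left out gave 3212, 3855 and 2034 calls, with 6 WT and 9 *mak-2* lists.

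Leaving out 1 array at a time gave 2782 to 3213 WT calls, 3331 to 3828 *mak-2* calls, 1552 to 1983 indirect calls, an overlap of 1812 to 2078, r of −0.662 to −0.641 across genes, 6 to 8 WT lists, 8 to 10 *mak-2* lists and −3.66 to −3.23 for the deleted gene.

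With the replicate number as a block (duplicateCorrelation, consensus 0.127) 2919, 3534 and 1605 genes were called, and 2780, 3408 and 1339 when arrays of one number were averaged. In the WT comparison, where pairing by number is likely, averaging ended the named calls of *mek-1* and *sub-1* and the block changed no other named call. In *mak-2*, where no pairing by number showed, *frq*, *acu-15* and *cat-4* lost their calls.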

Other observations

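The tests in this part, of gene families by symbol stem and of probes outside the gene tests, were chosen only after the data were seen.

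Genes for protein import into mitochondria fell at low Pi and rose in *mak-2*. Of 10 *tim* genes of the inner membrane translocases 9 fell (median −0.86, adjusted p = 0.000315, adjusted p = 0.0883 with an estimated correlation), *tim23* (NCU00371, −1.40) and *tim17* (NCU05623, −1.10) the most, and all 10 rose in *mak-2* (median 0.86, adjusted p = 0.00137, adjusted p = 0.114 with an estimated correlation). All 7 *tom* genes of the outer membrane translocase fell (median −0.87, adjusted p = 0.00597), *tom22* (NCU00431, −1.60) and *tom20* (NCU06632, −1.34) the most, and 6 of 7 rose in *mak-2* (median 0.82, adjusted p = 0.0171, adjusted p = 0.0846 with an estimated correlation), *tom20* (1.66) and *tom40* (NCU01179, 1.54) the most. All 8 *cyt* genes fell at low Pi (median −0.80, adjusted p = 0.000903) and 6 of 8 rose in *mak-2* (median 0.60, adjusted p = 0.0244, adjusted p = 0.133 with an estimated correlation). All 3 families rose in *mak-2*, while most of the respiratory chain genes of complex I fell there.

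Of 6 *ad* genes of purine synthesis 5 fell at low Pi (median −1.32, adjusted p = 0.0101, adjusted p = 0.134 with an estimated correlation), *ad-5* (NCU02629, −2.02) and *ad-3A* (NCU03166, −1.69) the most. In *mak-2* 4 of them rose and none fell (median 1.57, adjusted p = 0.0617). Of 16 *tca* genes 7 fell and 2 rose at low Pi (median −0.42, adjusted p = 0.124). In *mak-2* 13 rose and 2 fell (median 0.70, adjusted p = 0.0221, adjusted p = 0.363 with an estimated correlation), with *tca-5* (NCU03857, 1.42) and *tca-8* (NCU01227, 1.40) rising the most. Of 24 probes of the mitochondrial genome 13 fell and 1 rose in *mak-2* (median −0.88, adjusted p = 0.00733, adjusted p = 0.666 with an estimated correlation). These came from 44 families screened.

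The 28S rRNA probe had −2.55 ± 1.43 (SD) in *mak-2*, below 0 on all 8 arrays (exact p = 0.0078, adjusted p = 0.125 over 56 tests), the 18S probe −2.32 ± 1.95 (SD, 1 of 8 above 0) and the 5.8S probe −1.40 ± 1.66 (SD, 3 of 8 above 0). These probes varied widely between arrays, the 28S probe from −4.04 to 3.52 in the WT comparison.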
